A study of Homo sapiens with 12 samples.

How the data were processed

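RNA sequencing of total RNA measured transcript levels in 12 libraries of K562, a human chronic myeloid leukaemia line: 3 parental clones, 3 clones whose mutant ASXL1 allele was knocked out with CRISPR/Cas9, 2 pools with the SCR control guide, 2 pools with a FOXK1 guide and 2 pools with a FOXK2 guide. The deposited tables list 58233 genes each, labelled FPKM per the file headers. FPKM usually means fragments scaled to transcript length and library size, but the headers do not say how these values were scaled. The authors also deposited log2 fold changes, p-values and adjusted p-values for 3 comparisons, which are quoted here only where they are named as theirs. Their processing notes name the GRCh38.p10 build, TopHat, Bowtie, RSEM, edgeR and Cufflinks, without a version or a role for each. A second sheet of the ASXL1 table held 6597 of the same genes, with 0 values different from the full table, and was used only for that check. The SCR values were identical in the FOXK1 and the FOXK2 table.

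Read counts were not used here, and no counting interval or detection floor is given. In each library 94.1% to 100% of the low values above 0 were whole multiples of 1 step. That step ran from 0.0095 to 0.01036 over the libraries, and 0% of the values were multiples when shifted. Scaling each gene to its own length would give genes different steps, so levels of different genes may not be comparable as FPKM. If the step is 1 fragment, counts and depth could be derived from it, which was not done. As no counts were used, the test planned for counts gave way to the fallback named beside it in the plan. FPKM were taken as deposited, 1 was added, and log2 values were fitted with limma 3.58.1 in R 4.3.3 with a variance trend and without robust moderation. A gene was tested when at least as many libraries as the smaller group held 1 FPKM or more. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Each knockout was fitted with its own control, and the FOXK2 pools were set against the FOXK1 pools in a joint fit of the 6 pools. Adding 1 shrinks the fold change of genes with a low FPKM, and against a group listed at or near 0 the added amount sets its size. Nothing beyond the labels shows that the clones and pools are separate cultures, and every p-value measures the spread between these libraries. Replicate numbers were not used as pairs: the deviations of same-numbered libraries from their group means had correlations across genes from -0.13 to 0.08.

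Gene groups came from 34 lists written from general knowledge before the data were examined, and lists with at least 5 tested members were tested. They cover glycolysis, the pentose phosphate pathway, the TCA cycle, nuclear-encoded and mitochondrially encoded respiration genes, hypoxia, JAK-STAT signalling, the PR-DUB and FOXK complex, PRC1 and PRC2, HOX genes, globins, haem and iron, erythroid, megakaryocyte, granulocyte and monocyte, stem cell, lymphoid and adherent cell markers. The others hold tumour suppressors, the BCL2 family, G1/S, G2/M, MYC and ribosome biogenesis, ribosomal proteins, interferon-stimulated genes, antigen presentation, autophagy and lysosome, stress responses, cholesterol and fatty acid synthesis, WNT, immediate early genes, heat shock, histones and DNA damage. Each list was tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. At that setting, splits that mixed parental and mutant ASXL1 knockout libraries also passed 3 to 13 lists each, although such splits keep part of the real difference. Camera sets the members against all other tested genes, so its direction can differ from the sign of the members' median. Camera with an estimated correlation and fry, which asks whether members move one way without comparing them with other genes, were run beside it. Counts of members are given over all tested genes and adjusted over the list alone.

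Named genes followed a rule fixed at the same time: the targeted genes and their paralogues; the 8 largest rises and 8 largest falls among called genes of at least 2 FPKM whose groups do not overlap, without clone-based names; up to 4 members of each list with the smallest adjusted p; 5 genes per direction for FOXK2 against FOXK1; and up to 8 shared genes per direction. Some genes that the rule gives are left out, among them LUZP6 and PIGY, which overlap other genes, and copies of the U2 small nuclear RNA gene. Gene positions came from GENCODE 29. Python 3.11.15 with numpy 2.4.6 prepared the tables, and matplotlib 3.10.9 drew the figures.

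The test was tested on simulated data with changes planted in 67, 67 and 66 genes at log2 sizes of 0.5, 1 and 2. It recovered 50.7%, 86.6% and 98.5% of them in the ASXL1 layout, with 4.85% of its calls false. In the FOXK1 layout it recovered 40.3%, 76.1% and 93.9% with 5.41% false, and in the FOXK2 layout 29.9%, 77.6% and 93.9% with 8.84% false. In the layout of FOXK2 against FOXK1 it recovered 38.8%, 77.6% and 89.4% with 6.80% false. Alternatives tried were another amount added before the log (0.1 FPKM), no filter and a stricter filter on FPKM, a required fold change of 2, a replicate block, median-ratio and upper-quartile scaling, no variance trend, robust moderation, joint and separate fits, and leaving out each library. Tests that need read counts were not run. Single-gene values of 4 list members are not reported here.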

Results

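Transcripts were measured by RNA sequencing in 12 libraries of K562, a human chronic myeloid leukaemia cell line with erythroid features. They comprised 3 parental clones, 3 clones with the mutant ASXL1 allele knocked out, and 2 pools each with the SCR control guide, a FOXK1 guide or a FOXK2 guide. The summed FPKM per library ran from 824692 to 975657, and 13348 to 13681 genes per library reached 1 FPKM. Levels are mean FPKM ± SD over 3 clones or 2 pools, and fold changes are differences of log2(FPKM + 1) with limma's standard error (SE) and adjusted p.

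The series sets out to find genes regulated by mutant ASXL1, FOXK1 and FOXK2, so the targeted transcripts were examined in each knockout. An edit that shifts the reading frame need not lower the transcript, so these levels check the labels only in part. ASXL1 (ENSG00000171456; GRCh38 chromosome 20, 32358330 to 32439319) encodes a chromatin protein that partners the deubiquitinase BAP1. It fell from 49.4 ± 9.36 FPKM in the parental clones to 29.4 ± 2.53 in the mutant ASXL1 knockout clones (log2 fold change -0.72, SE 0.14, adjusted p = 0.0142). All 3 knockout clones lay below all 3 parental clones. The authors' table gives ASXL1 a log2 fold change of -0.08 with an adjusted p of 0.436. The deposited notes do not say whether that table and the FPKM rest on the same quantification, so the fall of ASXL1 stays uncertain. Without mutant ASXL1 knockout replicate 3 the adjusted p here was 0.0542 (0.00612 to 0.0542 over all alternatives). Its paralogue ASXL2 was at 8.18 ± 0.612 and 9.25 ± 0.342 FPKM (log2 fold change 0.16, adjusted p = 0.207). For ASXL2 the authors' table gives a log2 fold change of 0.25 with an adjusted p of 0.00721. ASXL3 did not exceed 0.01 FPKM in these 6 libraries. FOXK2 (ENSG00000141568, chromosome 17, 82519713 to 82644662), a forkhead transcription factor gene, fell from 41.7 ± 1.34 FPKM in the SCR pools to 26.5 ± 1.45 in the FOXK2 pools (log2 fold change -0.64, SE 0.07, adjusted p = 0.0445). For FOXK2 the authors' table gives a log2 fold change of -0.59 with an adjusted p of 2.52e-17. FOXK1 (ENSG00000164916; chromosome 7, 4682309 to 4771443), its paralogue, was at 6.25 ± 0.0184 FPKM in the SCR pools and 5.83 ± 0.345 in the FOXK1 pools, which did not pass (log2 fold change -0.09, adjusted p = 0.648; the authors' table gives -0.26 and 0.0189). FOXK1 in the FOXK2 pools (log2 fold change 0.15, adjusted p = 0.485) and FOXK2 in the FOXK1 pools (-0.01, adjusted p = 0.926) did not pass either. The FOXK2 call was lost with no filter on low FPKM (adjusted p = 0.149), with a replicate block (0.0957), without a variance trend (0.105), and without sgSCR replicate 1 (0.272), sgSCR replicate 2 (0.313), sgFOXK2 replicate 1 (0.136) or sgFOXK2 replicate 2 (0.0869). Over all alternatives its adjusted p ran from 0.0179 to 0.313.

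**Figure D1:**
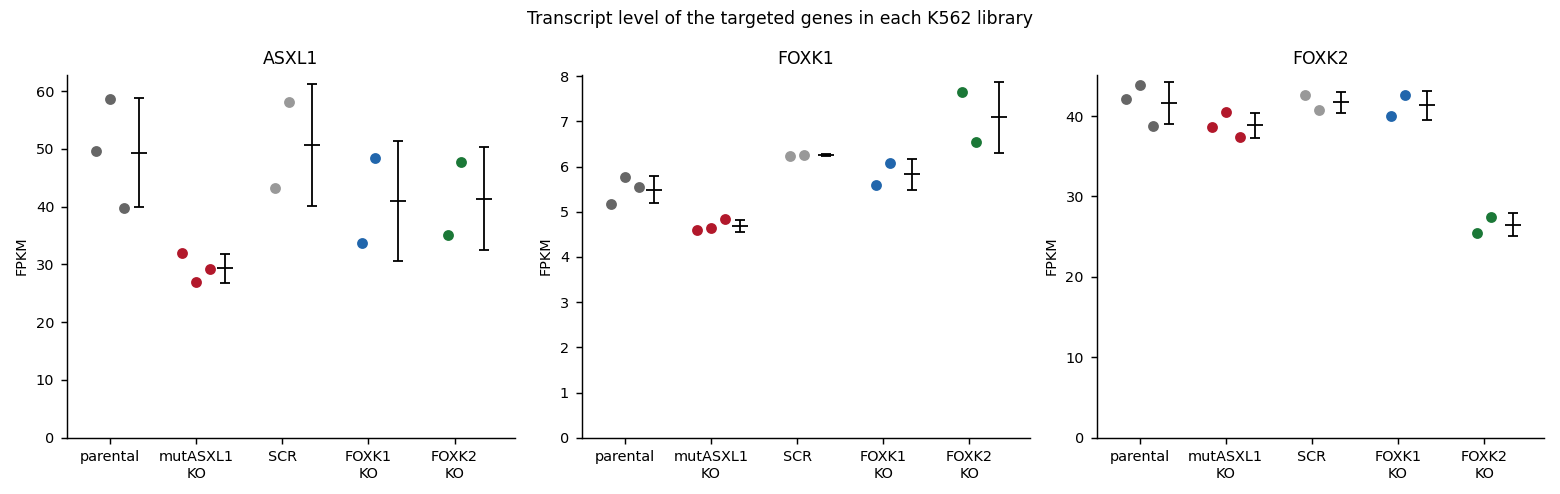
FPKM of ASXL1, FOXK1 and FOXK2 (y axes, linear from 0) in each of the 12 libraries, grouped on the x axis by parental, mutant ASXL1 knockout, SCR, FOXK1 knockout and FOXK2 knockout. Points are libraries, and dash and bar are mean ± SD. ASXL1 was lowest in the 3 mutant ASXL1 knockout clones (26.9 to 32.0 FPKM), and FOXK2 in both FOXK2 pools (25.5 and 27.5 FPKM).

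The mutant ASXL1 knockout clones were set against the parental clones to ask which transcripts the mutant allele regulates. The immediate early transcription factor genes FOS and EGR1, which growth signals induce, fell. FOS went from 42.7 ± 2.44 to 4.42 ± 0.622 FPKM (log2 fold change -3.02, SE 0.10, adjusted p = 0.000146). EGR1 went from 108 ± 9.26 to 27.7 ± 1.55 (-1.93, SE 0.08, adjusted p = 0.000146). AHSP, which encodes a chaperone of free alpha globin, fell from 46.8 ± 8.06 to 10.9 ± 3.79 FPKM (log2 fold change -2.05, SE 0.26). PAGE5, a cancer-testis antigen gene, rose from 1.02 ± 0.580 to 70.9 ± 2.71 FPKM (log2 fold change 5.19, SE 0.21). The fibronectin gene FN1 rose from 21.1 ± 2.77 to 103 ± 11.8 FPKM (2.24, SE 0.12). HECW2, a ubiquitin ligase gene, and CPZ, a carboxypeptidase gene, rose by log2 2.88 and 2.79 to 20.4 ± 2.57 and 17.0 ± 2.58 FPKM. The SCR and FOXK pools held 31.1 to 54.9 FPKM of FOS, 124 to 155 of EGR1, 0.46 to 2.31 of PAGE5 and 13.7 to 23.4 of FN1. HIST2H2AA3 rose from at most 0.01 FPKM in any parental clone to 39.6 ± 12.8, but its near-identical copy HIST2H2AA4 fell from 401 ± 96.6 to 174 ± 27.1. Their sum was 401 ± 96.6 in the parental and 214 ± 38.0 in the knockout clones.

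Genes of mitochondrial respiration were lower on balance in the mutant ASXL1 knockout. Of 45 nuclear-encoded oxidative phosphorylation genes, 35 fell and 0 rose (39 and 2 adjusted over the list alone; camera adjusted p = 2.95e-11, adjusted p = 0.530 with an estimated correlation). The cytochrome c oxidase gene COX6C fell from 494 ± 35.9 to 317 ± 14.6 FPKM (log2 fold change -0.64, SE 0.06), and UQCRH, of complex III, fell by 0.46. Of 13 mitochondrially encoded transcripts 12 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 9.93e-07, adjusted p = 0.530 with an estimated correlation). MT-CO3 fell by 0.62 and MT-CO2 by 0.67 on the log2 scale. Mitochondrially encoded transcripts made up 10.7% to 11.04% of the summed FPKM in the knockout clones and 13.3% to 15.0% in the parental clones. In the TCA cycle 13 of 25 members fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 0.00159, adjusted p = 0.530 with an estimated correlation). IDH2, the mitochondrial isocitrate dehydrogenase gene, fell from 47.5 ± 0.392 to 26.3 ± 1.19 FPKM (log2 fold change -0.83, SE 0.06).

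Sterol synthesis, mitosis, ribosomal protein and erythroid genes were the other groups lower on balance. In cholesterol and fatty acid synthesis 17 of 32 members fell and 1 rose (21 and 1 adjusted over the list alone; camera adjusted p = 6.88e-06, adjusted p = 0.530 with an estimated correlation). SQLE, the squalene epoxidase gene, fell from 99.1 ± 10.6 to 55.8 ± 5.14 FPKM (log2 fold change -0.82, SE 0.10), and MVD and FDPS of the mevalonate pathway fell by 0.66 and 0.51. Of 35 G2/M genes 16 fell and 0 rose (18 and 1 adjusted over the list alone; camera adjusted p = 6.91e-05, adjusted p = 0.530 with an estimated correlation). The spindle checkpoint kinase gene BUB1 fell by 0.46, and AURKB fell by 0.37. Of 44 cytosolic ribosomal protein genes 15 fell and 2 rose (22 and 2 adjusted over the list alone; camera adjusted p = 0.000372, adjusted p = 0.530 with an estimated correlation). In haem synthesis and iron handling 8 of 20 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 0.0332, adjusted p = 0.536 with an estimated correlation). UROS, of the haem pathway, fell from 38.4 ± 4.61 to 19.9 ± 1.03 FPKM (log2 fold change -0.91). Among 32 erythroid regulator and membrane genes 15 fell and 3 rose (16 and 4 adjusted over the list alone; camera adjusted p = 0.0332, adjusted p = 0.536 with an estimated correlation). XK, a membrane protein gene of the Kell blood group complex, rose from 2.72 ± 0.475 to 8.64 ± 0.130 FPKM (log2 fold change 1.38).

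Stress response and cytokine signalling genes were higher on balance in the mutant ASXL1 knockout. In the list of the integrated stress response, which slows translation under stress, and the unfolded protein response 12 of 36 members rose and 3 fell (15 and 3 adjusted over the list alone; camera adjusted p = 6.27e-05, adjusted p = 0.530 with an estimated correlation). TRIB3, a pseudokinase gene induced by ATF4, rose from 71.4 ± 0.233 to 139 ± 15.1 FPKM (log2 fold change 0.95, SE 0.08). STC2 rose from 14.5 ± 1.59 to 30.7 ± 0.899 (1.04, SE 0.09) and DDIT3 from 48.4 ± 6.46 to 79.2 ± 4.77 (0.71, SE 0.10). Of 23 heat shock genes 9 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 6.84e-05, adjusted p = 0.530 with an estimated correlation). The chaperone gene HSPA1A rose from 88.6 ± 5.23 to 147 ± 15.3 FPKM. JAK-STAT genes counted 9 higher and 4 lower of 32, the same adjusted over the list alone (camera adjusted p = 0.0332, adjusted p = 0.530 with an estimated correlation). Those that rose included SOCS1, SOCS2 and CISH, feedback inhibitors of the pathway, by log2 1.24, 0.86 and 0.84. In the BCL2 family and apoptosis list 4 of 28 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0412, adjusted p = 0.530 with an estimated correlation). The anti-apoptotic gene BCL2 went from 0.807 ± 0.0774 to 3.33 ± 0.518 FPKM (log2 fold change 1.25, SE 0.14). These 12 lists kept the sign of their median under median-ratio and upper-quartile scaling, and with median-ratio scaling 11 of them still passed, 4 upward and 7 downward. The list lost was cytosolic ribosomal proteins (camera adjusted p = 0.0739, and 0.0167 with upper-quartile scaling), with 9 members lower against 15, and TCA cycle members lower went from 13 to 8.

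**Figure D2:**
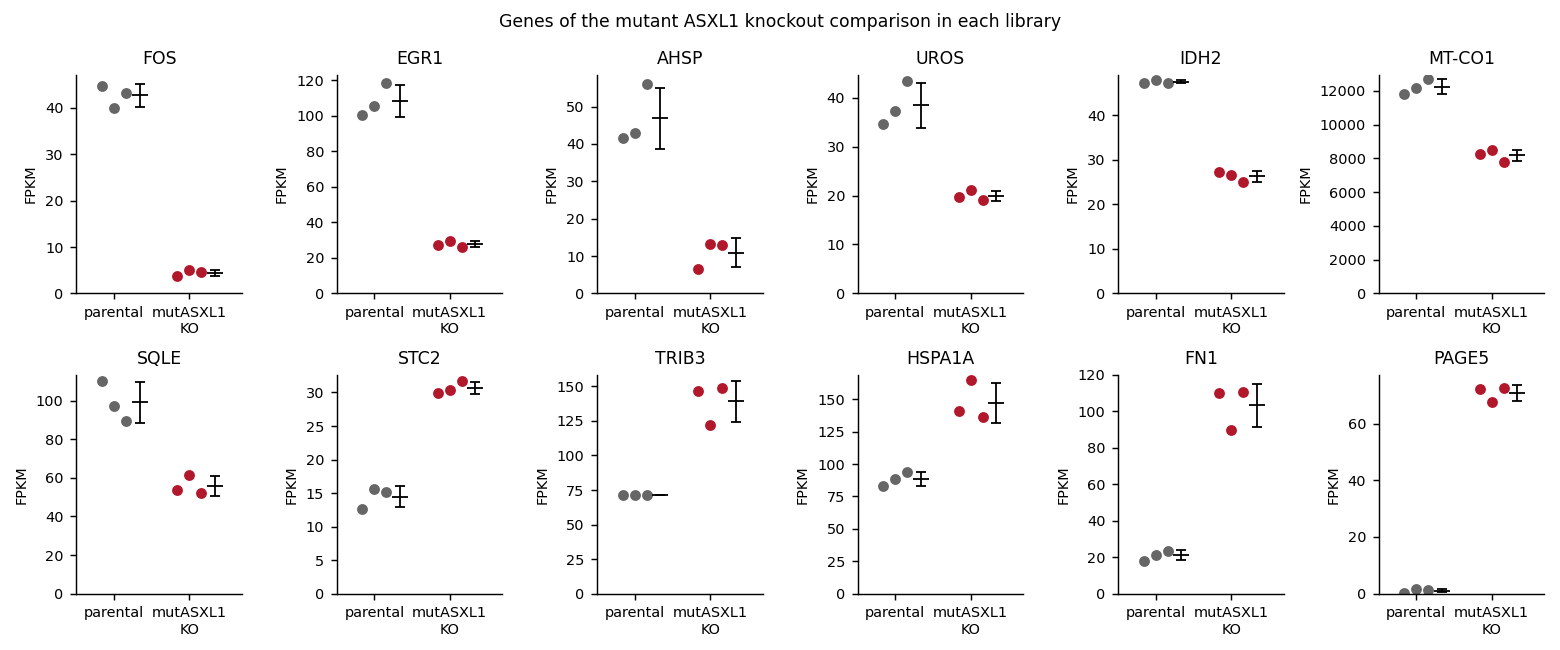
FPKM (y axes, linear from 0) of 12 genes in the 3 parental and 3 mutant ASXL1 knockout clones (x axes); points are libraries, and dash and bar are mean ± SD. FOS fell from 42.7 to 4.42 FPKM and PAGE5 rose from 1.02 to 70.9 FPKM, with no overlap between the groups.

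The other 22 lists did not pass camera (camera adjusted p from 0.129 to 0.963), although 10 of them passed fry, which does not compare members with other genes. They had 61 members higher and 70 lower of 425 tested (68 and 82 adjusted over each list alone). Globins split. HBB, the adult beta globin gene, rose from 6.94 ± 4.30 to 26.9 ± 6.10 FPKM (log2 fold change 1.93, adjusted p = 0.0130). Among 9 members 2 rose and 1 fell, and the fetal HBG2 did not pass (log2 fold change -0.47, adjusted p = 0.196). Of 17 HOX and cofactor genes 3 rose and 0 fell. HOXB4 was listed at 0 in every parental clone and at 3.26 ± 0.545 FPKM in the knockout, beside 2.84 and 3.37 in the SCR pools. Immediate early genes counted 5 higher and 7 lower of 22, with KLF10, a transcription factor gene, rising by log2 0.89 beside the falls of FOS and EGR1. In glycolysis 4 rose and 4 fell of 26: the lactate transporter gene SLC16A1 rose by log2 0.61 and GAPDH fell by 0.40. Tumour suppressors counted 8 higher and 3 lower of 32, with TXNIP, a brake on glucose uptake, rising from 79.3 ± 2.58 to 178 ± 19.4 FPKM. Granulocyte and monocyte genes counted 1 higher and 2 lower of 9, and SPI1, the myeloid master regulator, fell from 22.5 ± 1.71 to 10.4 ± 0.342 FPKM. Stem cell genes counted 2 higher and 2 lower of 7, megakaryocyte genes 0 and 2 of 14 (0 and 0 adjusted over the list alone). Lymphoid markers counted 1 and 2 of 6, and adherent cell markers 3 and 2 of 8. Counts of higher and lower members were 1 and 4 of 10 in the pentose phosphate pathway, 3 and 1 of 24 in hypoxia, 1 and 1 of 14 in the PR-DUB and FOXK complex. Such counts were 1 and 3 of 32 in PRC1 and PRC2, 2 and 8 of 36 in G1/S, and 4 and 6 of 34 in MYC and ribosome biogenesis. They were 4 and 5 of 18 among interferon-stimulated genes, 2 and 0 of 9 in antigen presentation, 3 and 6 of 38 in autophagy and lysosome, 7 and 4 of 24 in WNT, 1 and 5 of 19 among histones, and 3 and 2 of 17 in DNA damage. In 8 of these 22 lists, globins, glycolysis and MYC and ribosome biogenesis among them, the signs of median, mean and test differed.

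Across 13597 tested genes limma called 3039, of which 1075 were higher and 1964 lower in the mutant ASXL1 knockout, and 127 and 99 of these by at least 2-fold. The groups did not overlap in 42.9% of genes, where chance gives 10%, and 2507 of the calls have the same direction and an adjusted p under 0.05 in the authors' table. The count was 1947 with no filter on low FPKM, 1824 with a replicate block, and 1477, 1377 and 1346 without parental replicate 2, mutant ASXL1 knockout replicate 1 or mutant ASXL1 knockout replicate 3. With median-ratio scaling 51% of 2818 calls were higher, against 35.4% as deposited.

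The FOXK1 pools were set against the SCR pools to ask which transcripts FOXK1 regulates. PHGDH, the first enzyme of serine synthesis, fell from 151 ± 5.10 to 31.2 ± 2.70 FPKM (log2 fold change -2.24, SE 0.08, adjusted p = 0.00411). The asparagine synthetase gene ASNS fell from 203 ± 1.67 to 84.3 ± 1.87 (adjusted p = 0.00411) and the transcription factor gene ATF5 from 115 ± 0.255 to 24.7 ± 0.887 (-2.17, SE 0.05, adjusted p = 0.00166). In the integrated stress and unfolded protein response list 12 of 36 members fell and 1 rose (19 and 2 adjusted over the list alone; camera adjusted p = 5.13e-09, adjusted p = 0.487 with an estimated correlation). PSAT1, of serine synthesis, fell by 1.13 and TRIB3 fell by 1.09 on the log2 scale, and the growth regulator gene DDIT4 fell by 1.13. The member that rose, HSP90B1, a chaperone gene of the endoplasmic reticulum chosen after its values were seen, reached 226 ± 3.82 FPKM from 175 ± 2.77. ASS1, the argininosuccinate synthase gene, fell from 32.4 ± 0.301 to 3.72 ± 0.789 FPKM (log2 fold change -2.83, SE 0.13). The metallothionein genes MT2A and MT1X, whose products bind zinc and copper, rose from 6.71 ± 0.601 to 73.2 ± 1.73 FPKM (log2 fold change 3.27, SE 0.08) and from 24.2 ± 2.23 to 117 ± 6.17 (2.23, SE 0.08). IL1RAPL1, a synaptic adhesion gene, was listed at 0 in both SCR pools and at 41.8 and 43.6 FPKM in the FOXK1 pools, while 1 parental clone held 11.1 FPKM.

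Globin genes rose in the FOXK1 pools, 5 of 9 members with 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 5.69e-06, adjusted p = 0.487 with an estimated correlation). HBA2 rose from 1165 ± 14.1 to 1871 ± 61.3 FPKM (log2 fold change 0.68, SE 0.04), and the fetal globin gene HBG2 by log2 0.77. In heat shock 3 of 23 members rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.85e-05, adjusted p = 0.487 with an estimated correlation). HSP90AA1 rose from 528 ± 2.14 to 712 ± 1.00 FPKM. Histone genes counted 3 higher and 0 lower of 19 (13 and 1 adjusted over the list alone; camera adjusted p = 2.98e-05, adjusted p = 0.487 with an estimated correlation). Cholesterol and fatty acid synthesis counted 2 and 0 of 32 (15 and 1 adjusted over the list alone; camera adjusted p = 1.42e-05, adjusted p = 0.487 with an estimated correlation). The sterol enzyme gene HMGCS1 rose by log2 0.45. Glycolysis had 3 of 25 higher and 0 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.00547, adjusted p = 0.553 with an estimated correlation), with ENO2 rising by log2 0.87. MYC and ribosome biogenesis had 2 of 34 higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 1.64e-05, adjusted p = 0.514 with an estimated correlation). The set test also passed upward for oxidative phosphorylation, haem and G1/S without a called member. In these 38 of 45, 16 of 20 and 25 of 36 members had a positive fold change, and 2, 5 and 3 were higher adjusted over the list alone, beside 0, 0 and 1 lower (camera adjusted p = 2.6e-05, 0.00368 and 0.0234). With an estimated correlation these were adjusted p = 0.553, 0.514 and 0.514. Downward it passed for granulocyte and monocyte genes, 1 of 9 lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.0171, adjusted p = 0.487 with an estimated correlation). CD33 fell by 0.46. It also passed for JAK-STAT, 1 of 32 lower and 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 0.0205, adjusted p = 0.487 with an estimated correlation). STAT5A, a mediator of cytokine signals, fell by 0.61. Fry passed 3 lists in the FOXK1 pools, 2 upward and 1 downward.

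Among lists that did not pass, OGT, the O-GlcNAc transferase gene of the PR-DUB and FOXK complex, fell from 218 ± 7.39 to 122 ± 11.1 FPKM (log2 fold change -0.84, SE 0.08), the 1 lower of 14 members with 0 higher. IDH1 was the 1 lower of 25 TCA cycle genes, falling by 0.79. In hypoxia VEGFA and DDIT4 fell and EGLN3 rose among 24, in the erythroid list MYB fell and CA1 rose among 32. ITGA2B was the 1 lower of 13 megakaryocyte genes, and SESN2 the 1 lower of 17 DNA damage genes. These 6 lists did not pass camera (camera adjusted p from 0.177 to 0.850; 11 members higher and 9 lower adjusted over each list alone). In the other 16 lists limma called 0 of 335 members, with 71 at an unadjusted p under 0.05, and 5 higher and 8 lower adjusted over each list alone (camera adjusted p from 0.0757 to 0.936). The signs of median, mean and test differed in 2 of these 6 and 6 of these 16 lists.

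Limma called 250 of 13697 genes, 93 higher and 157 lower in the FOXK1 pools, 13 and 59 of them by at least 2-fold, and 3133 genes had an unadjusted p under 0.05. The pools did not overlap in 54.9% of genes, where chance gives 33.3%. The authors' table has 1284 genes higher and 1512 lower at an adjusted p under 0.05. Of limma's 250 calls, 226 are among them in the same direction. Limma's count was 10 with no filter on low FPKM, 37 with a replicate block, 34 with crossed replicate numbers as a block, 69 without a variance trend and 412 in a joint fit of the 6 pools. It was 0 without either sgSCR replicate 1 or sgSCR replicate 2 (2305 and 1889 genes at an unadjusted p under 0.05), 11 without sgFOXK1 replicate 1 and 5 without sgFOXK1 replicate 2.

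The FOXK2 pools were set against the same SCR pools to ask which transcripts FOXK2 regulates. PHGDH fell here too, to 35.9 ± 0.283 FPKM (log2 fold change -2.04, SE 0.05, adjusted p = 0.00701), and ATF5 fell to 31.5 ± 1.41 (-1.84, SE 0.06, adjusted p = 0.00808). ASNS fell to 88.5 ± 1.48 (-1.19, adjusted p = 0.0158) and ASS1 to 4.76 ± 1.24 (adjusted p = 0.0168). In the integrated stress and unfolded protein response list 6 of 36 members fell and 0 rose (15 and 2 adjusted over the list alone; camera adjusted p = 4.04e-07, adjusted p = 0.631 with an estimated correlation). OGT fell to 116 ± 3.88 FPKM (log2 fold change -0.90, SE 0.06), and OGT and FOXK2 itself were the 2 lower of 14 PR-DUB and FOXK complex genes, with 0 higher. MT2A rose to 25.6 ± 1.10 FPKM (log2 fold change 1.79, SE 0.09) and MT1X to 46.4 ± 2.66 (0.91, SE 0.09). These levels lie inside the range of the parental clones (12.1 to 36.3 and 31.3 to 56.0 FPKM), while both SCR pools lie below every parental clone. TEX19, a germline gene, and SLC7A8, an amino-acid transporter gene, rose by log2 1.17 and 1.05 to 11.6 ± 0.766 and 18.9 ± 0.0113 FPKM.

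Histone, globin, sterol, heat shock, ribosome biogenesis, haem, erythroid and respiration lists were higher on balance in the FOXK2 pools, with few members called singly. Fry passed 3 lists in the FOXK2 pools, 0 upward and 3 downward, so these rises rest on camera at the preset correlation. Histones had 0 called of 19, 18 with a positive fold change, and 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.04e-07, adjusted p = 0.631 with an estimated correlation). Globins had 0 called of 9, 8 positive, and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00101, adjusted p = 0.631 with an estimated correlation). HBG2 was at 13120 FPKM in the SCR and 21260 FPKM in the FOXK2 pools (log2 fold change 0.69, adjusted p = 0.0531). In cholesterol and fatty acid synthesis 1 of 32 rose, HMGCS1 by log2 0.43, and 0 fell (14 and 1 adjusted over the list alone; camera adjusted p = 6.74e-06, adjusted p = 0.631 with an estimated correlation). In heat shock 1 of 23 rose, HSP90AA1 by log2 0.40, and 0 fell (11 and 1 adjusted over the list alone; camera adjusted p = 6.56e-05, adjusted p = 0.631 with an estimated correlation). The set test also passed upward for MYC and ribosome biogenesis with 0 called of 34 (6 and 0 alone), and for haem with 0 of 20 (5 and 0 alone), both with these counts adjusted over the list alone. Their camera adjusted p = 0.00021 and 0.000733, and adjusted p = 0.631 with an estimated correlation for both. It passed for the erythroid list, 25 of 32 positive with MYB the 1 lower by 0.70 (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0392, adjusted p = 0.637 with an estimated correlation). Oxidative phosphorylation passed with 32 of 45 positive and 0 called, also adjusted over the list alone (camera adjusted p = 0.0411, adjusted p = 0.815 with an estimated correlation). Downward it passed for granulocyte and monocyte genes with 0 called of 8 (2 lower and 0 higher adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.631 with an estimated correlation). JAK-STAT passed downward with STAT5A, which fell by 0.52, the 1 lower of 32 (6 lower and 0 higher adjusted over the list alone; camera adjusted p = 0.0318, adjusted p = 0.637 with an estimated correlation).

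IDH1 was the 1 lower of 25 TCA cycle genes and VEGFA the 1 lower of 24 hypoxia genes, falling by 0.76 and 0.93. With the PR-DUB and FOXK complex these 3 lists did not pass camera (camera adjusted p from 0.294 to 0.980; 1 higher and 6 lower adjusted over each list alone). In the other 20 lists limma called 0 of 427 members, with 88 at an unadjusted p under 0.05, and 6 higher and 21 lower adjusted over each list alone (camera adjusted p from 0.0523 to 0.980). The DNA damage list passed fry downward (adjusted p = 0.0448), as did the PR-DUB and FOXK complex list, which holds the targeted FOXK2 itself and has 8 of 14 members positive. The signs of median, mean and test differed in 1 of these 3 and 5 of these 20 lists.

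Limma called 139 of 13672 genes, 20 higher and 119 lower in the FOXK2 pools, 10 and 57 of them by at least 2-fold, and 2828 genes had an unadjusted p under 0.05. The pools did not overlap in 54.0% of genes, where chance gives 33.3%. The authors' table has 950 genes higher and 1567 lower at an adjusted p under 0.05. Of limma's 139 calls, 115 are among them in the same direction. Limma's count was 0 with no filter on low FPKM (3496 genes at an unadjusted p under 0.05), 39 with a replicate block, 52 without a variance trend and 284 in a joint fit of the 6 pools. It was 0 without either sgSCR replicate 1 or sgSCR replicate 2 (1906 and 1495 genes at an unadjusted p under 0.05), 6 without sgFOXK2 replicate 1 and 15 without sgFOXK2 replicate 2.

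**Figure D3:**
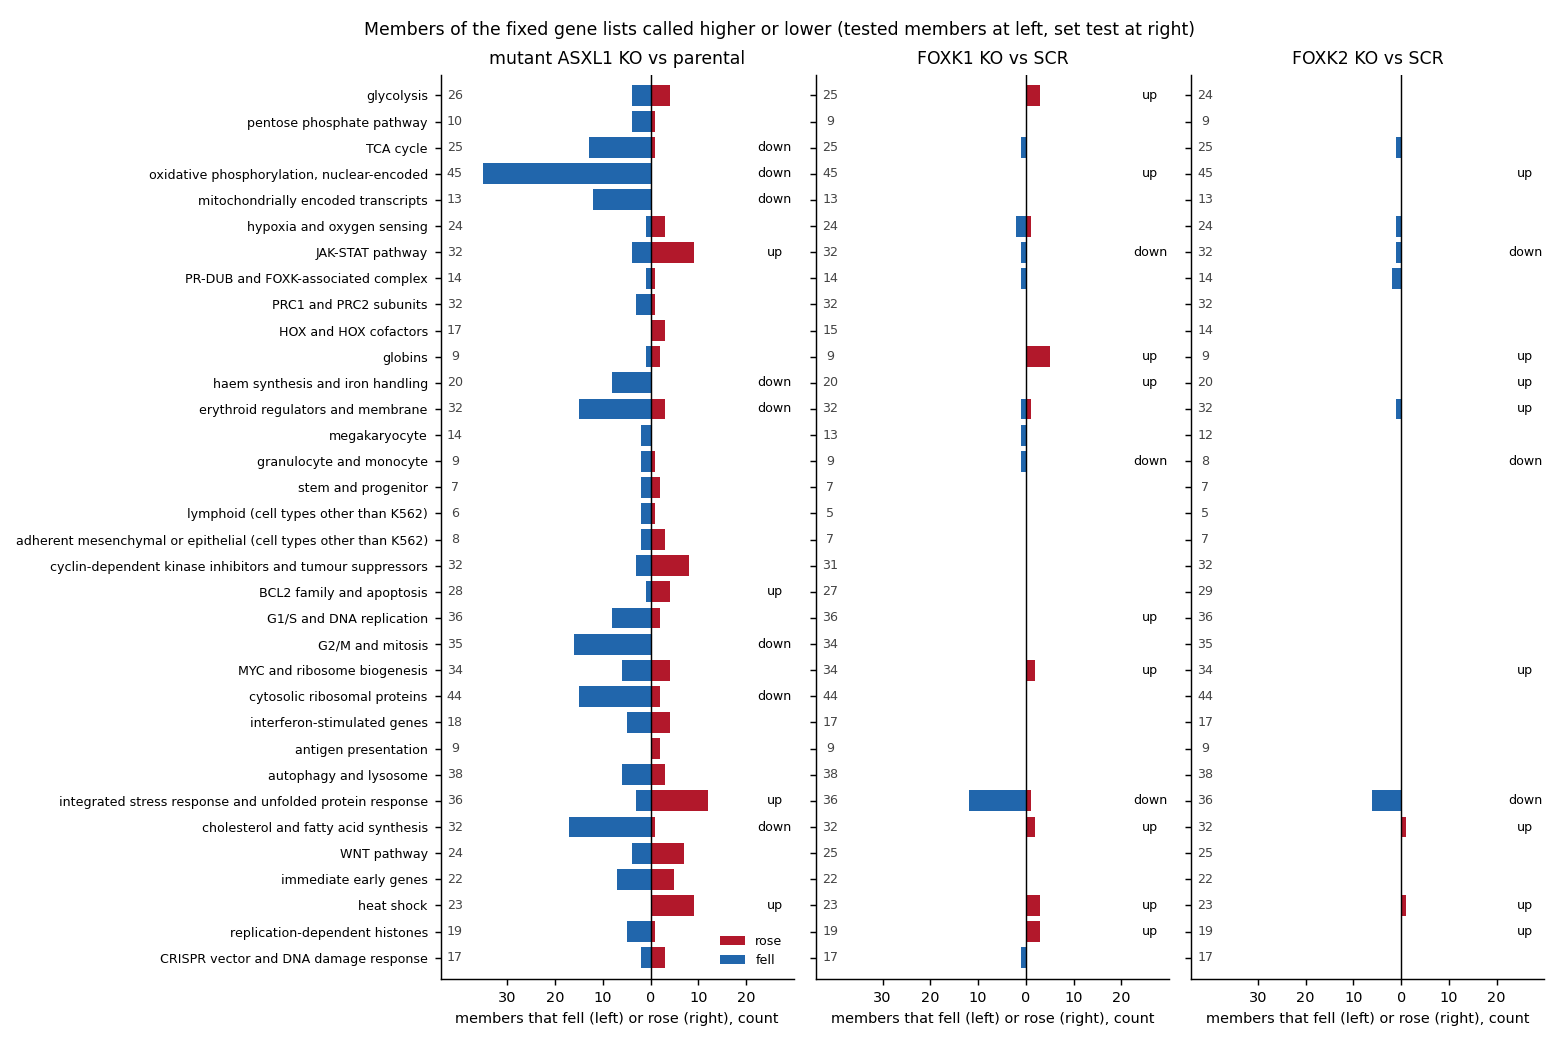
Number of called members of each of the 34 lists (x axes, genes; lower to the left, higher to the right) in the 3 comparisons with a control, with tested members at the left and "up" or "down" where the camera adjusted p was under 0.05. Lower oxidative phosphorylation genes (35 of 45) stand out in the mutant ASXL1 knockout, and lower stress response genes (12 and 6 of 36) in the FOXK1 and FOXK2 knockouts.

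The FOXK1 and FOXK2 knockouts were compared to ask whether both factors act on the same transcripts. Of 13455 genes tested in both, 102 were called in the same direction, 14 higher and 88 lower, and 0 in opposite directions, where independent lists give 1.51 in the same direction. Shared genes that fell include PHGDH, ATF5, ATP2A3, a calcium pump gene (log2 fold change -1.77 and -1.69), and ACSM3, an acyl-CoA synthetase gene (-1.08 in both). Shared genes that rose include EEF1A2, an elongation factor gene, and HEMGN, an erythroid nuclear protein gene, the latter by log2 0.49 and 0.51. Because both share the SCR pools, 100 simulations of unchanged groups against shared controls were run. They gave a mean of 0.02 shared calls (at most 1) and a mean correlation of fold changes across genes of 0.50 (at most 0.56), beside an observed Pearson r of 0.73 and Spearman rho of 0.73. The covariance of fold changes was 0.0797, beside 0.0215 simulated, and genes are not independent replicates. The simulations drew each gene in each library independently around the SCR mean. They therefore cannot exclude a departure that many genes of the SCR pools share, and do not separate it from effects of both knockouts. The shared count was 0 with no filter on low FPKM, 21 with a replicate block, 30 without a variance trend, 219 in a joint fit. It was 0 without either sgSCR replicate 1 or sgSCR replicate 2, 6 and 3 without sgFOXK1 replicate 1 or sgFOXK1 replicate 2, and 5 and 8 without sgFOXK2 replicate 1 or sgFOXK2 replicate 2.

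Tested directly, 5 of 14055 genes differed between the FOXK2 and the FOXK1 pools, 1 higher and 4 lower, and 903 had an unadjusted p under 0.05. CHAC1, a glutathione-degrading enzyme gene induced by ATF4, was higher in the FOXK2 pools, 17.2 ± 0.0728 against 5.98 ± 0.395 FPKM (log2 fold change 1.38, SE 0.08, adjusted p = 0.0169). The SCR pools held 21.8 ± 1.34. MT2A and MT1X were lower in the FOXK2 than in the FOXK1 pools (log2 fold change -1.48 and -1.32, adjusted p = 0.0122 and 0.0230), although above the SCR pools in both. IL1RAPL1 was lower (adjusted p = 0.000291), at 0.04 and 0 FPKM in the FOXK2 pools, so its log2 fold change of -5.42 is set by the 1 FPKM added before the log and was -8.50 with 0.1 FPKM added. Lower too was the clone-named AC022296.2, chosen after its values were seen, which held 13.96 and 12.36 FPKM in the FOXK1 pools and was listed at 0 in the other 10 libraries. The stress response list was higher in the FOXK2 than in the FOXK1 pools (1 of 36 higher, 0 lower; 5 and 1 adjusted over the list alone; camera adjusted p = 0.00205, adjusted p = 0.786 with an estimated correlation). Glycolysis was lower with 0 of 25 called (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00214, adjusted p = 0.872 with an estimated correlation). Adherent cell markers were lower with 0 of 7 called (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0112, adjusted p = 0.786 with an estimated correlation). In the other 31 lists 0 of 717 members were called, with 58 at an unadjusted p under 0.05 in limma and 3 higher and 4 lower adjusted over each list alone (camera adjusted p from 0.0997 to 0.939). Fry passed 0 of the 34 lists in this direct comparison. The count of 5 was 2 with no filter on low FPKM, 2 with a replicate block, 12 without a variance trend, and 1 and 2 without sgFOXK1 replicate 1 or sgFOXK1 replicate 2. Of 15 alternatives, CHAC1 and MT1X lost their calls in 9 each and MT2A in 6, among them the removal of any 1 of the 4 FOXK libraries (adjusted p up to 0.180, 0.264 and 0.183). AC022296.2 lost its call in 3, without either FOXK1 library and with 0.1 FPKM added before the log (adjusted p up to 0.158), and IL1RAPL1 in 0.

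**Figure D4:**
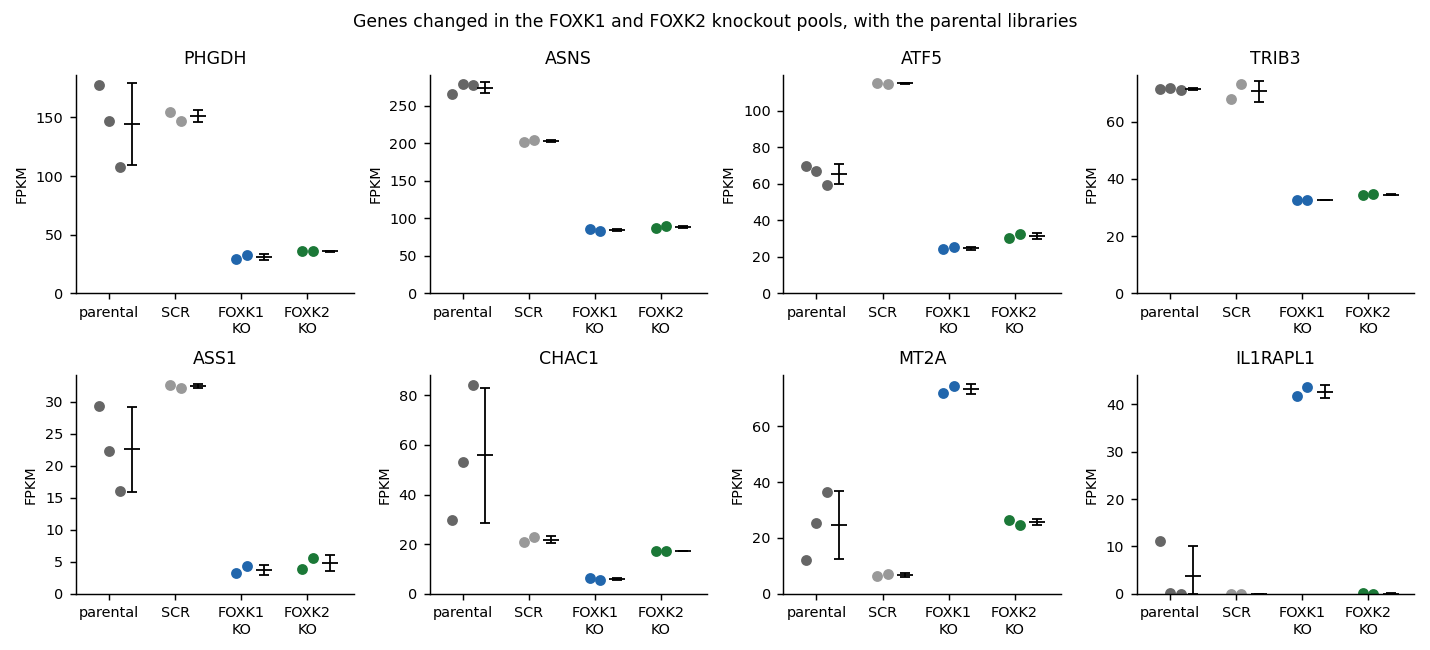
FPKM (y axes, linear from 0) of 8 genes in the parental clones and in the SCR, FOXK1 knockout and FOXK2 knockout pools (x axes). Points are libraries, and dash and bar are mean ± SD. PHGDH held 147 and 155 FPKM in the SCR pools and 29.3 to 36.2 in the 4 knockout pools, and IL1RAPL1 was above 1 FPKM only in the FOXK1 pools and 1 parental clone.

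The mutant ASXL1 knockout was set beside the FOXK knockouts to ask whether they change the same transcripts, since the series names them together. With FOXK1, 77 of 13143 genes were called in both: 19 in the same direction (29.7 if independent) and 58 in opposite directions (24.8 if independent). Without parental replicate 3 these were 30 and 53. Of the opposite genes 35 were higher in the mutant ASXL1 knockout and lower in the FOXK1 pools, among them TRIB3, STC2, INHBE, an activin subunit gene, and SHMT2, the mitochondrial serine hydroxymethyltransferase gene. INHBE rose from 13.01 ± 1.25 to 50.04 ± 6.07 FPKM in the mutant ASXL1 knockout and fell from 10.1 ± 0.401 to 0.881 ± 0.104 in the FOXK1 pools. The other 23 went the opposite way, such as MT1X, which fell from 44.3 ± 12.4 to 19.2 ± 1.09 FPKM in the mutant ASXL1 knockout, and S100A4, a calcium-binding protein gene. With FOXK2, 36 of 13144 genes were called in both, 11 in the same (18.9 if independent) and 25 in opposite directions (11.5 if independent), and without parental replicate 3 they were 18 and 24. Fold changes across all genes had a Pearson r of -0.09 with FOXK1 and -0.10 with FOXK2 (Spearman rho -0.07 and -0.04), and genes are not independent replicates. The shared count with FOXK1 was 1 with no filter on low FPKM, 9 with a replicate block, 13 without a variance trend. It fell to 0 without either sgSCR replicate 1 or sgSCR replicate 2, 3 without sgFOXK1 replicate 1 and 1 without sgFOXK1 replicate 2. It was 34, 37 and 40 without parental replicate 2, mutant ASXL1 knockout replicate 1 and mutant ASXL1 knockout replicate 3. With FOXK2 the shared count was 0 with no filter on low FPKM, 8 with a replicate block, 7 without a variance trend, and 0 without either SCR pool. It was 2 and 4 without sgFOXK2 replicate 1 or sgFOXK2 replicate 2, 19 without parental replicate 2, and 22 without mutant ASXL1 knockout replicate 1 or mutant ASXL1 knockout replicate 3.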

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

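The tests of scaling between libraries, of the SCR control, of a cell state shared with the parental clones and of IL1RAPL1 before the guide were chosen only after the result was seen.

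Lower respiration transcripts in the mutant ASXL1 knockout: 47 of 58 nuclear and mitochondrially encoded members were called lower, with a median log2 fold change of -0.36. After removing a trend of fold change on transcript length and expression level over 13545 genes, the members' median was -0.22 (bootstrap 95% range -0.26 to -0.17; trend alone -0.16), so length and level do not account for the whole of it. With median-ratio scaling 39 of the 47 were still called lower, and with upper-quartile scaling 44, which argues against scaling between libraries as the whole cause. Loss of the mutant allele and other differences between the knockout and the parental clones stay open, and no value here separates them.

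Lower stress response transcripts in the FOXK pools: all 12 members called lower (12 in FOXK1, 6 in FOXK2) lay below every parental clone in all 4 knockout pools. For CHAC1, ASNS, PSAT1, SESN2, CTH, STC2, DDIT4 and GDF15 both SCR pools already lay below every parental clone, so a fall from the SCR level fixed this outcome. For TRIB3 and SLC7A5 the SCR pools straddled the lowest parental clone (67.86 and 73.24 against 71.19 FPKM, and 106.8 and 112.8 against 110.3). A fall from the SCR level nearly fixed the outcome for these too. For ATF5 and PHGDH the outcome was not fixed and argues against a raised SCR control as the whole cause. Both SCR pools lay above every parental clone for 1 member, ATF5 (115.2 and 114.8 FPKM against 59.27 to 69.95). Scaling between libraries is argued against too, since all 18 calls were kept under both scalings. A cell state varying among the parental clones was tested in 4 successive forms, each set after the result of the one before: 83.3% of all 102 genes called in both FOXK knockouts matched in sign the loading on the clones' first principal component, in the orientation with more matches, then members and other genes were taken apart, then the component was oriented by 12780 genes called in neither knockout (60.06% of them match; 85.4% of the 96 other genes and 3 of the 12 members match, 9 in the reverse orientation), and last came a test free of orientation. In that test 1 shift along the component accounted for 11.6% (FOXK1) and 0.277% (FOXK2) of the members' sum of squares. The bootstrap upper bounds were 64.8% and 27.3%, where both had to stay under 50%. So for the members the state cannot be told apart from a FOXK effect. The FOXK2 bound stayed under 50%, but the FOXK1 bound allows over 50% of the sum of squares on the component. For the other genes the state may account for part of their change. Loss of FOXK1 or FOXK2 and outgrowth of particular cells in the pools stay open and untested.

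Genes switched on or off: counting 5 FPKM or more as on and under 0.5 as off, 1 gene was on in all 3 mutant ASXL1 knockout clones and off in all parental clones, HIST2H2AA3, whose sum with its near-identical copy HIST2H2AA4 fell from 401 to 214 FPKM, and 1 gene, the clone-named AC087072.1, was the reverse. Genes switched in a single clone numbered 60 among the knockout and 70 among the parental clones, so a recent common founder of the knockout clones cannot be told from separate origins. IL1RAPL1 differed between the FOXK pools (log2 fold change -5.42, FOXK2 minus FOXK1, and -8.50 with 0.1 FPKM added before the log), and 1 parental clone held 11.1 FPKM of it, so cells with IL1RAPL1 on before the guide was added may be the source of its level in the FOXK1 pools. Loss of FOXK1 as its cause stays open and untested.

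AC022296.2, listed at 0 in the FOXK2 pools, differed between the FOXK pools in the direct test, with a log2 fold change (FOXK2 minus FOXK1) whose size is set by the amount added before the log, -3.82 with 1 FPKM and -7.05 with 0.1 FPKM. For MT2A that difference was -1.48, with both pools above the SCR pools. For CHAC1 it was 1.38, with both pools below the SCR pools. For MT1X it was -1.32, with both pools above the SCR pools.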

How the results depend on the processing

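The tests with scalings, both filters on FPKM, no variance trend, robust moderation, crossed numbers as a block or the 4 knockout libraries alone, and 0.1 FPKM for shared genes, were chosen only after the result was seen. The others were planned. A lone library left in a group is assumed to vary like the others. A required fold shrinks a count by construction, and for the other changes the cause was not tested.

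With no filter on low FPKM, calls were 1947 (ASXL1), 10 (FOXK1), 0 (FOXK2; 3496 genes at an unadjusted p under 0.05 in limma) and 2 (FOXK2 against FOXK1). Then 1 targeted gene passed, and shared calls were 0 (FOXK1 and FOXK2), 1 (ASXL1 and FOXK1) and 0 (ASXL1 and FOXK2). Requiring a 2-fold change, calls were 226, 72 and 67 for the 3 knockouts, targeted genes 0, and shared calls 40, 11 and 8. With a replicate block they were 1824, 37, 39 and 2, targeted genes 1, and shared calls 21, 9 and 8. Without a variance trend they were 69 (FOXK1), 52 (FOXK2) and 12 (FOXK2 against FOXK1), targeted genes 1, and shared calls 30, 13 and 7. The joint fit gave 412 (FOXK1), 284 (FOXK2) and 219 shared, and crossed numbers as a block gave 34 (FOXK1). With median-ratio scaling 51% of 2818 ASXL1 calls were higher, against 35.4%.

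Leaving out 1 library gave 1346 to 2696 calls for ASXL1, 0 to 11 for FOXK1, 0 to 15 for FOXK2 and 1 to 5 for FOXK2 against FOXK1. Targeted genes passing were 1 to 2, and shared calls 0 to 8 (FOXK1 and FOXK2), 0 to 83 (ASXL1 and FOXK1) and 0 to 42 (ASXL1 and FOXK2). The 0s arose without sgSCR replicate 1 or sgSCR replicate 2, where limma still gave 2305 and 1889 genes (FOXK1) and 1906 and 1495 genes (FOXK2) at an unadjusted p under 0.05. Lists past the set test numbered 9 to 13, 11 to 13 and 8 to 12 for the 3 knockouts, beside 12, 12 and 11 with all libraries. With an estimated correlation they were 0, 0 and 0 (0, 2 and 1 at an unadjusted p under 0.05 in limma's camera), and with fry 22, 3 and 3.

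Of 4042 values of named genes under alternatives, 3031 kept direction and side of the threshold. Another 1009 kept direction but no longer passed. They were 247 of 2338 values for ASXL1, 469 of 1014 for FOXK1, 266 of 585 for FOXK2 and 27 of 105 for FOXK2 against FOXK1. The remaining 2 changed sign. Both were FOXK2 in the FOXK1 comparison (-0.01, not called), at 0.02 without sgSCR replicate 1 and 0.03 without sgFOXK1 replicate 1. Leaving out 1 library gave it -0.0574 to 0.0320. Stress response members called lower, 12 (FOXK1) and 6 (FOXK2), were 3 and 0 with no filter and 0 without either SCR library. For FOXK1 they were 7 with a replicate block or crossed numbers as a block, and 3 and 2 without sgFOXK1 replicate 1 or sgFOXK1 replicate 2. For FOXK2 they were 4 without a variance trend, 10 in the joint fit, and 2 and 3 without sgFOXK2 replicate 1 or sgFOXK2 replicate 2. Alternatives that need read counts were not run, and depth was not worked out.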

Other observations

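The tests by splits were chosen before the result was seen, while the genes common to 3 knockouts and the spread among clones were looked at only after the result was seen.

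Some changes were common to all 3 knockouts, although the mutant ASXL1 knockout shared fewer same-direction calls with each FOXK knockout than independent lists give. These numbered 19 against 29.7 for FOXK1 and 11 against 18.9 for FOXK2. Both FOXK comparisons also use the same SCR pools. TEX19, a germline gene, rose in the mutant ASXL1 knockout from 8.06 ± 2.46 to 20.1 ± 1.99 FPKM (log2 fold change 1.26, adjusted p = 0.00857). From 4.60 ± 0.375 FPKM in the SCR pools it rose to 12.2 ± 0.390 in the FOXK1 and 11.6 ± 0.766 in the FOXK2 pools, calls lost in 6 and 7 of 13 alternatives (adjusted p up to 0.226 and 0.246). CARS, the cysteine aminoacyl-tRNA synthetase gene, fell from 91.8 ± 2.49 to 74.8 ± 3.61 FPKM in the mutant ASXL1 knockout, a call lost without parental replicate 2 (adjusted p = 0.0558, 0.0112 to 0.0558 over all alternatives). It fell from 63.6 ± 0.487 FPKM in the SCR pools to 40.4 ± 0.921 and 42.5 ± 0.0665 in the FOXK1 and FOXK2 pools, calls lost in 7 of 13 alternatives each. ASNS had a log2 fold change of -0.21 in the mutant ASXL1 knockout (adjusted p = 0.0256), a call lost in 7 of 14 alternatives, against -1.25 and -1.19 in the FOXK1 and FOXK2 pools, calls lost in 3 and 4 of 13 alternatives (adjusted p up to 0.156 and 0.242).

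The parental clones differed from one another in several genes named above. DDIT4 ran from 348 to 847 FPKM, CHAC1 from 29.8 to 84.3, MT2A from 12.1 to 36.3 and PHGDH from 108 to 177 across them. Of 7538 genes with a mean of at least 10 FPKM in the parental clones, 128 had a highest clone at least 2 times the lowest, and of 7465 such genes in the mutant ASXL1 knockout clones 75 had. HBB held 23 to 33.9 FPKM in the mutant ASXL1 knockout clones, 3.49 to 11.8 in the parental clones and 3.53 to 9.62 in the SCR and FOXK pools.

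Other splits of the 6 parental and mutant ASXL1 knockout libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 3039 called genes, and the highest other split 2, so 1 of the 10 gave as many. It gave 12 lists past the set test, and 2 of the 10 gave as many: the split of parental replicate 1 with mutant ASXL1 knockout replicates 1 and 3 from the rest gave 13 lists while it called 1 gene. All remaining splits also passed lists, 3 to 6 each, while calling at most 2 genes. At the preset correlation, lists thus passed camera under each of the 10 splits. Every other split mixes parental and knockout clones in unequal parts. It so keeps part of the real difference, which also widens the spread within its groups. The other splits therefore do not show how many lists or genes pass where no difference exists. The real split gave 77 genes shared with FOXK1 (highest other 1) and 36 shared with FOXK2 (highest other 0), as many in 1 of the 10 splits each. The other splits called at most 2 genes and could share no more, so these shared counts say nothing about overlap between the knockouts. Groups of 2 pools were not split.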
